A study of Mus musculus with 6 samples.

How the data were processed

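Total RNA of sorted cells was extracted with a silica column micro kit, amplified with the NuGEN Ovation PicoSL WTA V2 system, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols; the sort gate is not given in the sources used here. The macrophages were precultured in 20 ng/ml M-CSF for 5 days and then kept for 6 days in 50 ng/ml M-CSF, in 20 ng/ml FSL-1, or in 20 ng/ml FSL-1 with 10 µM nutlin-3a. The labels leave open whether M-CSF was also present with FSL-1. Groups and replicate numbers were taken from the labels: 3 groups of 2 arrays. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

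The deposited values are log2 expression per probe set, made by the authors with RMA in Affymetrix Expression Console 1.4, per the submitters' processing notes; RMA corrects background, equalises the arrays by quantiles and summarises the probes of a probe set. This equalisation would hide a change shared by most genes. The median over all probe sets was 5.05 to 5.14 on the 6 arrays. No raw intensities or detection calls are used here, so the background level is unknown; probe sets without a gene name had a median level of 4.25, and all genes a median of 5.51.

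Of 34390 probe sets, 23521 name 1 gene, 1814 several and 9055 none in the platform annotation used. Those that name 1 gene gave 22180 genes; for the 1082 genes with more than 1 such probe set, the probe set with the highest mean over the arrays was kept. Entrez identifiers of 23328 probe sets were found in the RefSeq gene table (GRCm38.p6), which changed 0 symbols. Probe sets of 1 gene were called in opposite directions for D5Ertd579e with nutlin-3a and for Psd3 in FSL-1 + nutlin-3a against M-CSF. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed.

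Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 6 arrays, so that the groups shared 1 estimate of the spread, with 3 residual and 4.88 prior degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. A total of 25 gene lists, written before the data were examined, was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of each comparison; list members were also counted after adjustment over the list alone. A list of sex-linked genes was described without a test. Members under an older symbol were matched through the RefSeq synonyms, and members not among the 22180 genes are not analysed here. Lists share some genes, for example 4 between the osteoclast and matrix lists.

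The genes named in the text follow a rule fixed together with the lists: in each main comparison the 10 highest and 10 lowest changes among called genes whose groups did not overlap and whose brighter group lay above the median of all genes, up to 4 called members with the smallest p from each list, and a fixed set of genes around p53, TLR2, M-CSF and fusion. The third comparison has 5 in each direction. Predicted genes were passed over in the first part, 1 in each main comparison.

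The test was checked on simulated data built on the FSL-1 and M-CSF comparison, with 200 changed genes among 22180 in each of 20 runs. It called 34.8% of genes changed 1.5-fold, 97.2% of those changed 2-fold, 100% of those changed 4-fold and 0.0605% of unchanged genes. Over the runs these were 1340, 1340, 1320 and 439600 genes, so the last value is not the share of calls that were false. It does not show that false calls stayed within the adjusted p of 0.05. The 200 changed genes per run were also fewer than the 1521 called with FSL-1 in the data. A list with 15 of 30 genes raised 2-fold was called in 20 of 20 runs with the preset correlation. With an estimated correlation it was called in 11 of 20. Unchanged lists were called in 0 of 480 cases with the preset correlation. The simulated genes varied independently, whereas the estimated correlation was 0.341 in the real mitosis list and 0.554 in the interferon list. These runs therefore cannot show how either setting performs on lists of correlated genes.

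Alternatives fixed at the same time were eBayes with trend and robust, quantile normalization once more, centring of each array, the mean of a gene's probe sets, filters on dim genes, fits on the compared groups alone, the replicate number as a block, array weights, a fold minimum of 1.5 and leaving out each array in turn. A block with the M-CSF numbers crossed and a division of the FSL-1 arrays between the comparisons were added after seeing the data. Where an array is left out, its group has 1 array, which is assumed to vary like the others. If that group is not part of the comparison, the fit is the same as on the compared groups alone. With 2 arrays per group, tests for outlying samples and regroupings of samples were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.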

Results

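Gene expression was measured in cultured mouse macrophages on 6 arrays, 2 for each of 3 groups. Bone marrow cells of C57Bl/6 mice were first grown for 5 days in M-CSF, the growth factor that drives monocyte precursors to become macrophages. The macrophages were then kept for 6 days in M-CSF, in FSL-1, or in FSL-1 together with nutlin-3a. FSL-1 is a synthetic diacylated lipopeptide that activates the receptor pair TLR2 and TLR6, and the series design calls the FSL-1 cells multinucleated giant cells. Nutlin-3a blocks the binding of p53 to Mdm2, the ligase that marks p53 for degradation. Replicate arrays correlated at 0.9929 to 0.9951 across the 22180 genes (3 pairs), and arrays of different groups at 0.9788 to 0.9858 (12 pairs). The median SD between replicates was 0.106 (log2, n = 2) in M-CSF, 0.0917 in FSL-1 and 0.104 in FSL-1 + nutlin-3a. The number of arrays limits the precision of every value.

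The comparison of FSL-1 with M-CSF asked how gene expression of the giant cell cultures differs from that of macrophages kept in M-CSF. With FSL-1, Slc13a3, a sodium-dependent dicarboxylate transporter, rose 43.9-fold, from 5.79 ± 0.08 to 11.24 ± 0.14 (log2, mean ± SD, n = 2 each, probe set 17394461). Saa3, an acute-phase serum amyloid, rose 43.5-fold (probe set 17491193), Lox, the enzyme that cross-links collagen, 35.3-fold (probe set 17354367), and Mmp14, a membrane-bound metalloproteinase, 29.6-fold (probe set 17300279). Slc7a11, a subunit of the cystine importer, rose 26-fold (log2 change 4.70, SE 0.182, with 1.32 and adjusted p = 0.0577 at its other probe set), and Acod1, which makes itaconate, 23.5-fold (log2 change 4.55, SE 0.136). The other genes with the highest changes were Cd55 (4.44), Lancl3 (4.33), the formyl peptide receptor Fpr2 (4.32) and the chemokine Ccl12 (4.31); the other probe set for Lancl3 had a log2 change of 0.04. Decreases were smaller: Hpgd, which degrades prostaglandins, had a log2 change of -2.51 (SE 0.215), the laminin chain Lama3 -2.38, the iron exporter Slc40a1 -2.37, Arrdc3 -2.02, Plxdc2 -1.96, Cmah -1.89, Il12rb2 -1.81, Abcd2 -1.79 and Abcg3 -1.74. Adjusted p for these genes ran from 3.76e-06 for Slc13a3 to 0.00196 for Arrdc3 (limma).

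Of 22180 genes, 1521 passed an adjusted p of 0.05 with FSL-1, of which 867 rose and 654 fell. Changes over 2-fold were found in 274 genes that rose and 149 that fell, and changes over 4-fold in 81 and 4. In 50.2% of genes the groups did not overlap, against 33.3% by chance. The count of 1521 became 515 without M-CSF replicate 1, 451 without FSL-1 replicate 1 and 463 without FSL-1 replicate 2.

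**Figure D1:**
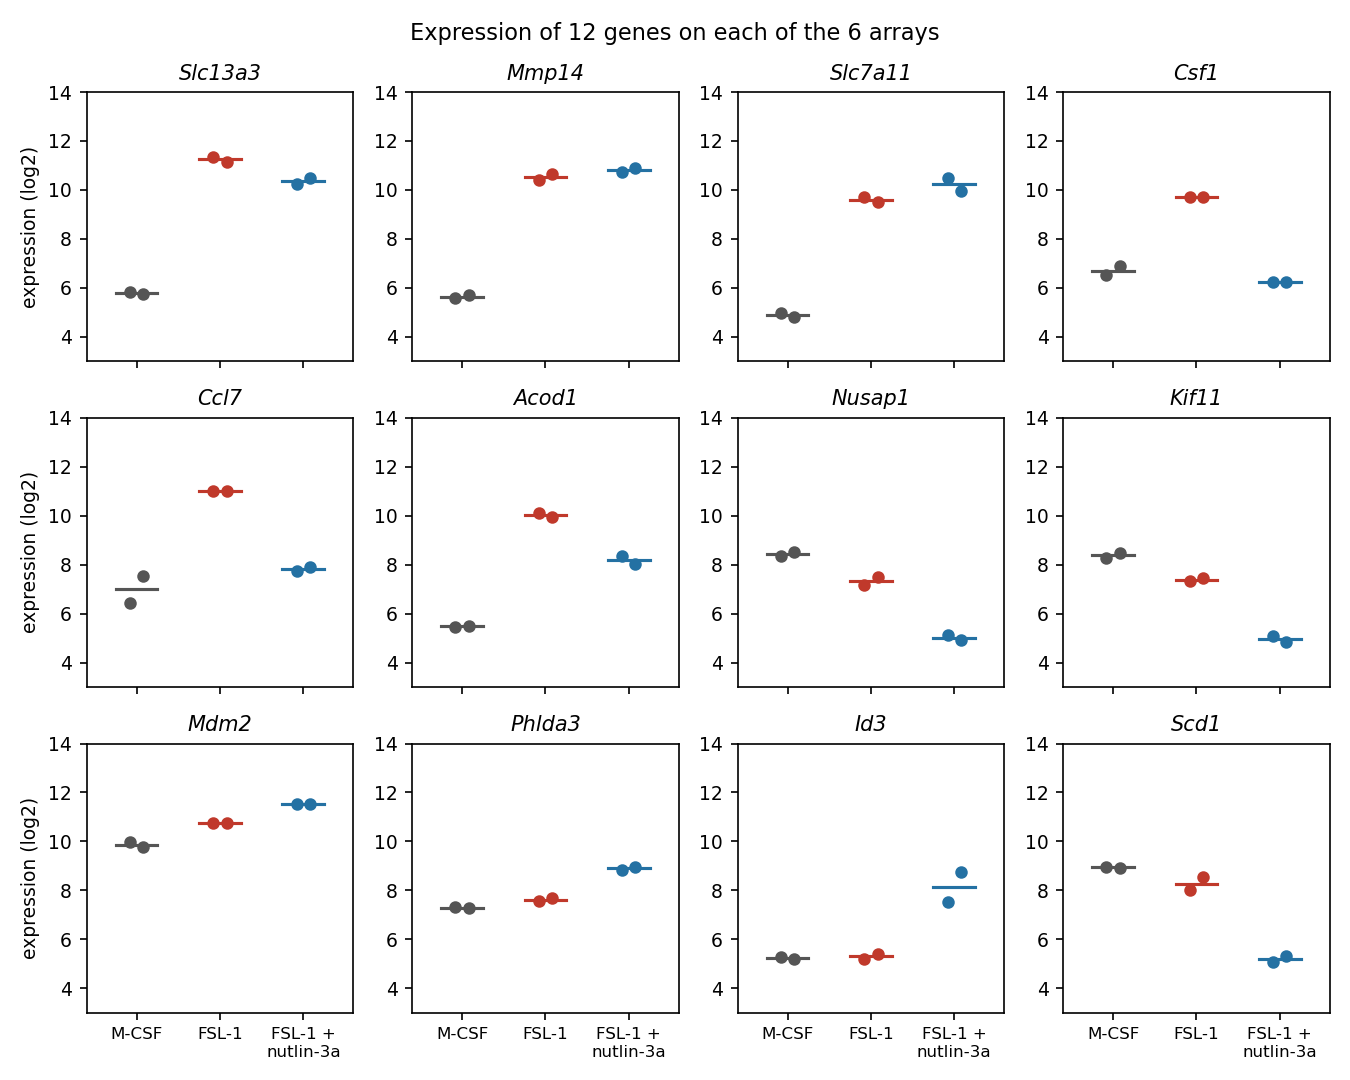
Expression (log2, vertical axes) of 12 genes on each array, with M-CSF in grey, FSL-1 in red and FSL-1 + nutlin-3a in blue; points are arrays and bars are group means (n = 2). Csf1 rose by 3.02 with FSL-1 and fell by 3.48 when nutlin-3a was added, while Mmp14 had changes of 4.89 and 0.30.

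Inflammatory genes rose as a group with FSL-1. Of 36 measured genes of the TLR and NF-kB list, 20 rose and 1 fell (26 and 1 adjusted over the list alone), with a median log2 change of 0.99. The list ranked above other genes (camera, adjusted p = 9.6e-25), and also did so with an estimated correlation (adjusted p = 0.0452). Among its members the scavenger receptor Marco had a log2 change of 3.92 (SE 0.125) and the interleukin-1 receptor antagonist Il1rn 3.90 (SE 0.173). The receptor genes themselves did not pass: Tlr2 had a log2 change of 0.39 (adjusted p = 0.123) and Tlr6 -0.36 (adjusted p = 0.106). Of 26 interferon response genes, 6 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 5.17e-07, adjusted p = 0.405 with an estimated correlation), among them Usp18 (1.43). When any 1 of the 4 compared arrays was left out, 1 to 4 interferon genes rose and 0 genes of the TLR and NF-kB list fell.

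Genes of the extracellular matrix rose too: 14 of 28 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.63, camera adjusted p = 2.07e-15, adjusted p = 0.0732 with an estimated correlation). The count of 14 was 9 without M-CSF replicate 1 or FSL-1 replicate 2, and the count of 1 was 0 without any 1 of the 6 arrays. Beside Lox and Mmp14, the collagenase Mmp8 rose by 2.51 (SE 0.131). The osteoclast and macrophage fusion list split. Of its 30 genes, 7 rose and 1 fell (10 and 2 adjusted over the list alone), including the bone-resorbing enzymes Acp5 (2.49, SE 0.168), Mmp9 (2.30) and Ctsk (1.99), while the median was 0.03. The fusion receptor genes were near the median level of all genes (5.51): Dcstamp had 5.36 ± 0.23 in M-CSF and 5.47 ± 0.32 in FSL-1 (log2 change 0.11, adjusted p = 0.813), and Ocstamp a change of 0.03 (adjusted p = 0.946). Both signs turned when M-CSF replicate 1 (Dcstamp -0.06, Ocstamp -0.12) or FSL-1 replicate 1 (-0.12 and -0.09) was left out. The list passed camera (adjusted p = 0.0178, adjusted p = 0.373 with an estimated correlation), but not after quantile normalization was applied once more (adjusted p = 0.0613). The count of 7 was 4 without FSL-1 replicate 1 and 3 without FSL-1 replicate 2, and the count of 1 was 0 without either.

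Genes of cell division fell with FSL-1. Of 37 mitosis genes, 21 fell and 0 rose (32 and 0 adjusted over the list alone), with a median log2 change of -0.68 (camera adjusted p = 1.29e-20, adjusted p = 0.195 with an estimated correlation). Of 24 cytokinesis genes, 11 fell and 0 rose (17 and 2 adjusted over the list alone, median -0.62, adjusted p = 5.17e-07, adjusted p = 0.336 with an estimated correlation). The centromeric histone Cenpa had a log2 change of -1.67 (SE 0.131), the central spindle motor Kif23 -1.38, the spindle protein Nusap1 -1.12, the kinetochore protein Ndc80 -1.04 and Kif14 -1.03. Cdk1, the mitotic kinase, had -0.38 (adjusted p = 0.139), and Ccnd1, a cyclin of early G1, 0.94 (adjusted p = 0.11). Of 35 replication genes, 1 fell and 0 rose (1 adjusted over the list alone, median -0.14, camera adjusted p = 0.0239, adjusted p = 0.697 with an estimated correlation), and the list no longer passed without FSL-1 replicate 1 (adjusted p = 0.281) or M-CSF replicate 2 (adjusted p = 0.971). Of 30 DNA damage genes 1 fell (1 adjusted over the list alone, median -0.18, camera adjusted p = 0.006, adjusted p = 0.439 with an estimated correlation, adjusted p = 0.0841 without FSL-1 replicate 1). The mitosis count of 21 became 10 without M-CSF replicate 1, 12 without M-CSF replicate 2, 5 without FSL-1 replicate 1 and 7 without FSL-1 replicate 2, and the cytokinesis count of 11 became 2, 2, 2 and 3. The replication and DNA damage counts of 1 became 0 in each of these fits.

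Stress response, NRF2, glycolysis and MYC lists ranked higher with FSL-1. Of 29 genes of the unfolded protein and integrated stress response, 16 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.64, camera adjusted p = 1.32e-16, adjusted p = 0.143 with an estimated correlation). Examples were the pseudokinase Trib3 (1.69, SE 0.161), the chaperone Dnajb9 (1.20) and Nupr1 (1.07). Of 20 NRF2 targets, 11 rose and 0 fell (13 and 1 adjusted over the list alone, median 0.52, adjusted p = 2.49e-10, adjusted p = 0.0706 with an estimated correlation), among them Gsta3 (2.71), Gclm, which serves glutathione synthesis (1.41), and Srxn1 (1.24). Of 25 glycolysis and hypoxia genes, 12 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.44, adjusted p = 6.3e-12, adjusted p = 0.143 with an estimated correlation), among them Ero1a (1.64), the glucose transporter Slc2a1 (1.51, with 0.17 and adjusted p = 0.56 at its other probe set) and Pfkfb3 (1.32). Of 29 MYC and ribosome biogenesis genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.34, adjusted p = 7.75e-10, adjusted p = 0.214 with an estimated correlation), with Myc at 2.02 (SE 0.259) and Gnl3 at 1.08. When 1 of the 4 compared arrays was left out, the stress count of 16 became 6 to 15, the NRF2 count of 11 became 7 or 8, the glycolysis count of 12 became 4 to 8 and the MYC count of 9 became 2 to 5. Cholesterol synthesis genes went the other way, with 2 of 20 lower (4 adjusted over the list alone, median -0.25, camera adjusted p = 0.00102, adjusted p = 0.439 with an estimated correlation, adjusted p = 0.059 without M-CSF replicate 2). This count of 2 became 0 or 1 when 1 of the 4 compared arrays was left out. Oxidative phosphorylation (3 of 28 rose, adjusted p = 0.0531), lipid handling (3 rose and 4 fell of 27, adjusted p = 0.44) and lysosome genes (3 of 28 rose, adjusted p = 0.445) did not pass, and these counts became 0 to 2, 1 to 4 and 0 to 2 when 1 of the 4 compared arrays was left out. Within the lipid list Fabp4 rose by 1.28 and the nuclear receptor Pparg had a log2 change of -1.13.

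Of 29 genes of resident and alternatively activated macrophages, 6 fell and 3 rose with FSL-1 (11 and 4 adjusted over the list alone, median -0.34, camera adjusted p = 0.00158, adjusted p = 0.143 with an estimated correlation). Maf, a macrophage transcription factor, had a log2 change of -0.97 (SE 0.123), the scavenger receptor Stab1 -0.95 and Tgfbi -0.94. Csf1r, the receptor for M-CSF, had -0.87 (SE 0.132, adjusted p = 0.00858), a call lost without M-CSF replicate 1, FSL-1 replicate 1 or FSL-1 replicate 2. The resident counts of 6 and 3 were 4 and 0, 3 and 0, and 4 and 0 without these 3 arrays. The MHC class II gene H2-Aa had -1.69, but the class II list did not pass (1 rose and 2 fell of 15, adjusted p = 0.884), and its median (0.02) and mean (-0.06) differ in sign. Its count of 2 became 1 when any 1 of the 6 arrays was left out, and its count of 1 became 0 without FSL-1 replicate 2. Of 38 p53 targets, 6 rose and 1 fell (8 and 3 adjusted over the list alone, median 0.07, adjusted p = 0.0531). Among them Plk2 rose by 1.45, Tnfrsf10b by 1.13 and Mdm2 by 0.88 (SE 0.122), while Sesn1 had -1.31; the Mdm2 call was lost without either FSL-1 array, and Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, had 0.40 (adjusted p = 0.148). The count of 1 that fell was 2 without M-CSF replicate 2, and the p53 count of 6 was 4 without either M-CSF array and 2 without either FSL-1 array. Of 21 senescence and cell cycle inhibitor genes, 2 rose and 6 fell (adjusted p = 0.279), with Cdkn2c at -1.25; the count of 6 became 2 or 3 and the count of 2 became 0 or 1 when any 1 of the 4 compared arrays was left out.

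Markers of other cell types were tested as well. Neutrophil markers rose in 4 of 16 and fell in 0 (4 and 1 adjusted over the list alone, median 0.13, camera adjusted p = 0.0203, adjusted p = 0.208 with an estimated correlation, adjusted p = 0.051 when the dimmest genes were filtered out). The count of 4 was 2 without M-CSF replicate 1, FSL-1 replicate 1 or either FSL-1 + nutlin-3a array. The calcium-binding protein S100a8 rose from 4.19 ± 0.42 to 6.60 ± 0.13 (log2, n = 2), and Mmp8 belongs to this list too. Fibroblast and stromal markers rose in 2 of 16 (3 adjusted over the list alone, median 0.28, camera adjusted p = 0.000938, adjusted p = 0.208 with an estimated correlation). Both, Vcam1 and Acta2, lost their call when any 1 of the 4 compared arrays was left out, and Acta2 also with the replicate number as a block. Without FSL-1 replicate 1, other members of the list were called instead. Dendritic cell (2 of 14 rose, adjusted p = 0.115), lymphocyte (1 rose and 1 fell of 16, adjusted p = 0.44), and erythroid, mast cell and megakaryocyte markers (1 rose and 1 fell of 14, adjusted p = 0.657) did not pass. The dendritic count of 2 became 0 without FSL-1 replicate 2 and 1 without any other of the 4 compared arrays, and the counts of 1 became 0 in 1 or more of these fits.

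**Figure D2:**
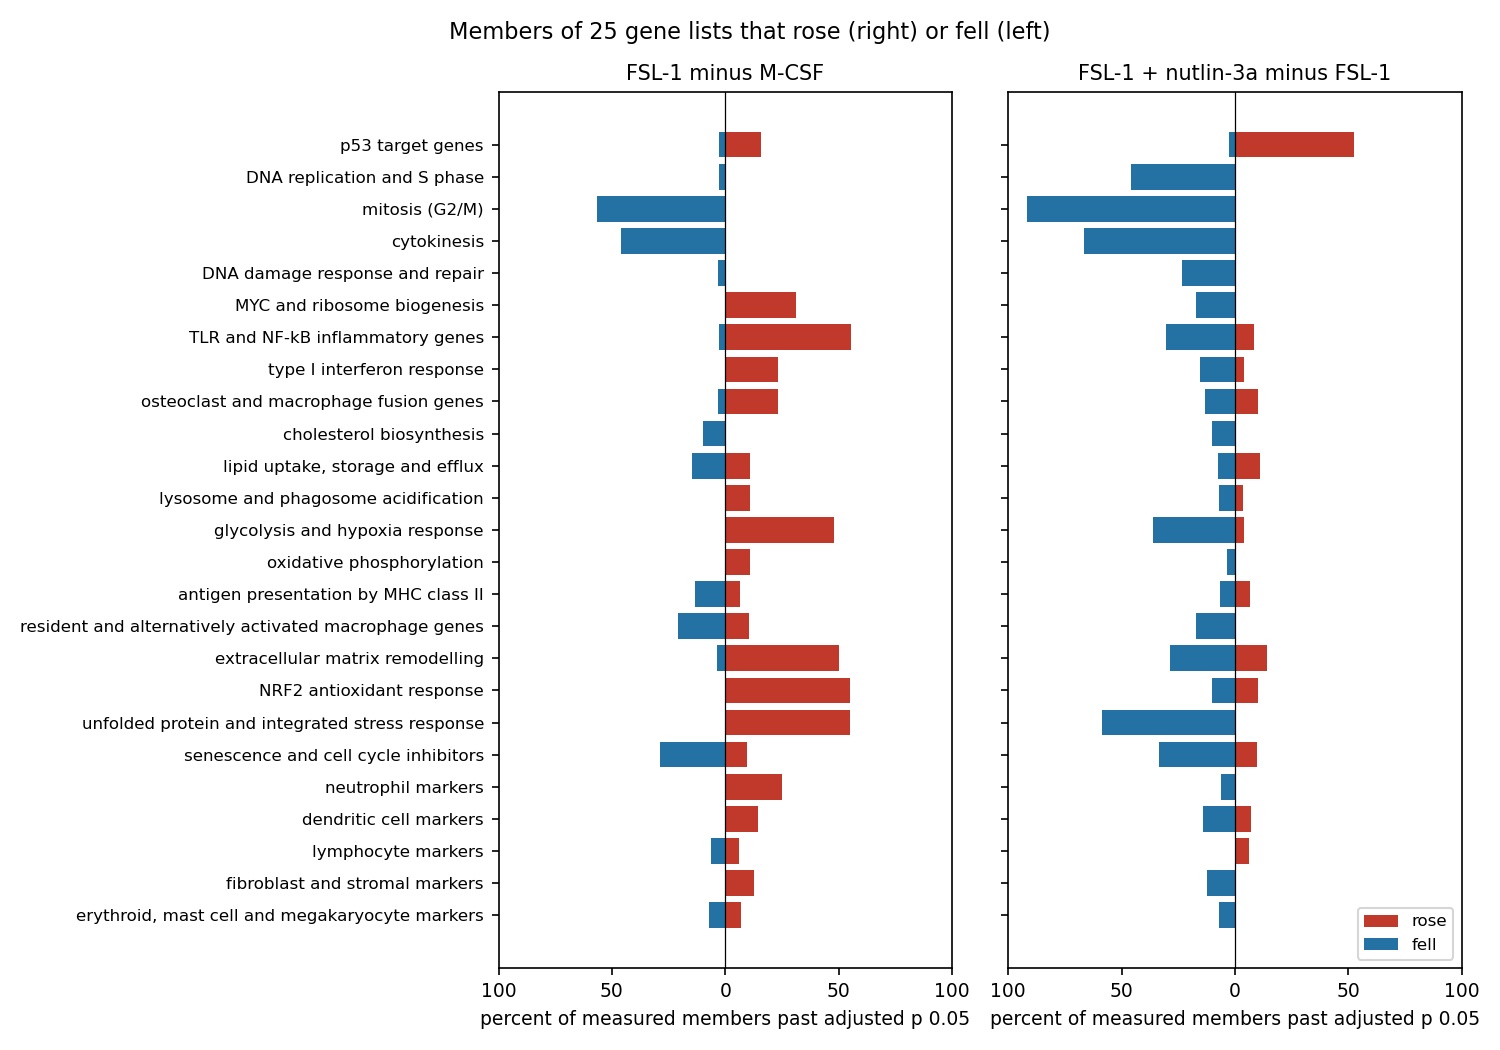
Percent of the measured members (horizontal axes) of each of 25 gene lists (vertical axis) that rose (red, right of 0) or fell (blue, left of 0) past an adjusted p of 0.05, for FSL-1 minus M-CSF (left) and FSL-1 + nutlin-3a minus FSL-1 (right). Of 37 mitosis genes, 21 fell in the left panel and 34 in the right, and of 38 p53 targets, 6 and 20 rose.

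The comparison of FSL-1 + nutlin-3a with FSL-1 asked what changes when nutlin-3a, given to raise active p53, is added to these cultures. The amount and activity of p53 protein were not measured on the arrays. The highest increases were in Id3, an inhibitor of basic helix-loop-helix factors, which rose 7.07-fold from 5.31 ± 0.15 to 8.13 ± 0.87 (log2, n = 2, probe set 17420016), the sulfatase Sulf2 (log2 change 2.48, SE 0.164), the lysosomal enzyme Hgsnat (2.39, SE 0.117), the integrin chain Itgal (2.03), Crip2 (1.95), Dmpk (1.95), the glutamate receptor subunit Gria3 (1.88) and the sorting receptor Sorl1 (1.85). Id1, related to Id3, had 2.15 (SE 0.284), a call lost without FSL-1 replicate 2. The strongest decreases were in Csf1, the gene of M-CSF itself, which fell by 3.48 (SE 0.146, probe set 17409075), the chemokines Ccl7 (-3.19) and Ccl12 (-3.09), the fatty acid desaturase Scd1 (-3.07, SE 0.181), the cytochrome oxidase subunit Cox6a2 (8-fold lower), the lectin receptor Clec4e (-2.88), the amino acid transporter Slc7a5 (-2.79), the cyclin Ccna2 (-2.78), the prostacyclin receptor Ptgir (-2.78) and Anln, an organiser of the contractile ring (-2.68). Adjusted p for these genes ran from 0.000119 for Csf1 to 0.00514 for Id1 (limma).

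Of 22180 genes, 1441 passed with nutlin-3a, of which 528 rose and 913 fell. Changes over 2-fold were found in 89 genes that rose and 285 that fell, and over 4-fold in 6 and 42. The groups did not overlap in 50.9% of genes, against 33.3% by chance. The count of 1441 became 362 and 352 without FSL-1 replicate 1 or 2, and 582 and 627 without FSL-1 + nutlin-3a replicate 1 or 2.

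Of 38 p53 targets, 20 rose and 1 fell with nutlin-3a (23 and 1 adjusted over the list alone), with a median log2 change of 0.60 (camera adjusted p = 8.3e-14, adjusted p = 0.289 with an estimated correlation). Phlda3, an inhibitor of Akt, rose by 1.28 (SE 0.117), Gtse1 by 1.26, Dcxr by 1.13 and Inka2 by 1.05. Mdm2 rose by 0.77 (SE 0.122, adjusted p = 0.0113), from 10.75 ± 0.01 to 11.52 ± 0.01 (log2, n = 2), and the call was lost without any 1 of the 4 compared arrays. Cdkn1a had 0.61 (adjusted p = 0.0431). This call was lost without any 1 of the 4 compared arrays, with the replicate number as a block and with each array centred on its median. It was also lost in the fit of the compared groups alone, which leaving out either M-CSF array repeats. Plk2 was the member that fell (-1.01). The count of 20 became 6 without FSL-1 replicate 1, 11 without FSL-1 replicate 2, 10 without FSL-1 + nutlin-3a replicate 1 and 12 without FSL-1 + nutlin-3a replicate 2. The p53 gene itself is not analysed here.

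Cell division genes fell further with nutlin-3a. Of 37 mitosis genes, 34 fell and 0 rose (36 and 0 adjusted over the list alone, median -1.48, camera adjusted p = 1.59e-42, adjusted p = 0.289 with an estimated correlation). The spindle motor Kif11 had a log2 change of -2.45 (SE 0.14), Nusap1 -2.32, Nuf2 -2.19 and the kinase Plk1 -1.77, and Cdk1 had -0.78 (adjusted p = 0.0131), a call lost without any 1 of the 4 compared arrays. Of 24 cytokinesis genes, 16 fell and 0 rose (19 and 1 adjusted over the list alone, median -1.17, adjusted p = 1.15e-19, adjusted p = 0.289 with an estimated correlation), with Shcbp1 at -2.61, Kif23 at -2.05 and Ect2 at -2.02. Of 35 replication genes, 16 fell and 0 rose (28 and 0 adjusted over the list alone, median -0.67, adjusted p = 1.13e-17, adjusted p = 0.289 with an estimated correlation); Rrm2, a subunit of ribonucleotide reductase, had -1.65, with -0.30 and adjusted p = 0.335 at its other probe set. Of 30 DNA damage genes, 7 fell and 0 rose (19 and 1 adjusted over the list alone, median -0.42, adjusted p = 4.15e-07, adjusted p = 0.289 with an estimated correlation). Without FSL-1 replicate 1, FSL-1 replicate 2, FSL-1 + nutlin-3a replicate 1 and FSL-1 + nutlin-3a replicate 2, the replication count of 16 became 2, 1, 6 and 3, and the DNA damage count of 7 became 1, 0, 3 and 1. The mitosis count stayed between 25 and 29 in these fits and the cytokinesis count between 11 and 16. Of 21 senescence and cell cycle inhibitor genes, 2 rose and 7 fell (adjusted p = 0.284), with Cdkn2c at -1.32; in these fits the count of 7 became 2 to 5 and the count of 2 became 0.

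The stress response list, higher with FSL-1, fell when nutlin-3a was added. Of 29 genes, 17 fell and 0 rose (25 and 3 adjusted over the list alone, median -0.77, camera adjusted p = 5.29e-19, adjusted p = 0.289 with an estimated correlation). Psat1, an enzyme of serine synthesis, had a log2 change of -2.37, Trib3 -2.32 (SE 0.161), the mitochondrial folate enzyme Mthfd2 -2.23 and Nupr1 -1.81. Glycolysis and hypoxia genes fell in 9 of 25 and rose in 1 (12 and 2 adjusted over the list alone, median -0.35, adjusted p = 1.16e-05, adjusted p = 0.289 with an estimated correlation), with Ndrg1 at -1.78, Pfkp at -1.32 and Ero1a at -1.05. MYC and ribosome biogenesis genes fell in 5 of 29 (10 adjusted over the list alone, median -0.24, adjusted p = 2.38e-05, adjusted p = 0.393 with an estimated correlation). Myc had -1.64 (SE 0.259), a call lost without FSL-1 replicate 1, FSL-1 replicate 2 or FSL-1 + nutlin-3a replicate 1. When 1 of the 4 compared arrays was left out, the glycolysis counts of 9 and 1 became 3 or 4 and 0 to 2, and the MYC count of 5 became 0 to 3. Cholesterol synthesis genes fell in 2 of 20 (5 adjusted over the list alone, median -0.19, camera adjusted p = 0.0155, adjusted p = 0.536 with an estimated correlation), a list call lost without FSL-1 replicate 2 (adjusted p = 0.0991). This count of 2 became 0 when any 1 of the 4 compared arrays was left out.

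Inflammatory genes were split by nutlin-3a. Of 36 genes of the TLR and NF-kB list, 11 fell and 3 rose (11 and 6 adjusted over the list alone, median -0.07, camera adjusted p = 0.026, adjusted p = 0.289 with an estimated correlation, adjusted p = 0.071 without FSL-1 replicate 2). Il1rn had -1.87, Acod1 -1.84 and the collagenase Mmp13 -1.67, while Marco had 0.45 (adjusted p = 0.0799). Extracellular matrix genes fell in 8 of 28 and rose in 4 (12 and 5 adjusted over the list alone, median -0.16, adjusted p = 0.0496, adjusted p = 0.404 with an estimated correlation), and the list call was lost without FSL-1 replicate 2 (adjusted p = 0.163) or FSL-1 + nutlin-3a replicate 2 (adjusted p = 0.0586). The crosslinking enzyme Tgm2 rose by 1.66 and Mmp2 by 1.08, while Lox had -1.48. The matrix count of 8 became 2 to 5, the count of 4 was 2 without either FSL-1 array, and the TLR count of 3 became 0 or 1, when 1 of the 4 compared arrays was left out. Interferon response genes fell in 4 of 26 and rose in 1 (5 and 1 adjusted over the list alone, median -0.15, adjusted p = 0.0103, adjusted p = 0.582 with an estimated correlation), a list call lost without FSL-1 replicate 2 (adjusted p = 0.409) or FSL-1 + nutlin-3a replicate 1 (adjusted p = 0.0645). The count of 1 was 0 without any 1 of the 6 arrays, and the count of 4 was 0 without FSL-1 replicate 2, 1 without FSL-1 + nutlin-3a replicate 1 and 0 without FSL-1 + nutlin-3a replicate 2. Fibroblast and stromal markers fell in 2 of 16 (4 adjusted over the list alone, median -0.20, adjusted p = 0.00569, adjusted p = 0.289 with an estimated correlation). Both, Acta2 and Col1a2, lost their call without FSL-1 replicate 2 or FSL-1 + nutlin-3a replicate 2, and Col1a2 also without FSL-1 + nutlin-3a replicate 1 and with the mean of its probe sets. The count of 2 was 4 without FSL-1 replicate 1, 0 without FSL-1 replicate 2, 1 without FSL-1 + nutlin-3a replicate 1 and 0 without FSL-1 + nutlin-3a replicate 2.

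The other lists did not pass camera with nutlin-3a. Adjusted p was 0.0575 for oxidative phosphorylation, 0.0915 for dendritic cell markers, 0.0961 for osteoclast and fusion genes, 0.104 for lysosome genes, 0.156 for lymphocyte markers, 0.34 for resident macrophage genes, 0.375 for neutrophil markers, 0.565 for MHC class II, 0.618 for NRF2 targets, 0.806 for erythroid, mast cell and megakaryocyte markers and 0.827 for lipid handling. Single members of these lists still passed: the lipid chaperone Fabp4 had -2.19, the nuclear receptor Nr1h3 1.02, the costimulatory molecule Cd86 -1.94 and the lipopolysaccharide receptor Cd14 -1.12. Ctsk had -1.30, a call lost without FSL-1 replicate 2 or FSL-1 + nutlin-3a replicate 2. Dcstamp (-0.09, adjusted p = 0.834) and Ocstamp (0.01, adjusted p = 0.974) did not pass, nor did Csf1r (0.40, adjusted p = 0.126), Tlr2 (0.22), Tlr6 (0.26) and Ccnd1 (0.83, adjusted p = 0.151).

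FSL-1 + nutlin-3a was also set against M-CSF, a comparison that does not use the FSL-1 arrays for its fold changes. The highest genes were Slc7a11 (log2 change 5.34, SE 0.182, and 1.81 at its other probe set), Mmp14 (5.19), Slc13a3 (4.58), Cd55 (4.51) and Marco (4.37). The lowest were Ccna2 (-3.79, SE 0.226), Scd1 (-3.73), the linker histone H1f5 (-3.66), Nusap1 (-3.43) and Kif11 (-3.43). In all 2110 genes passed, of which 1015 rose and 1095 fell, and 36 of 37 mitosis genes were lower (36 adjusted over the list alone, median -2.10, camera adjusted p = 1.83e-48, adjusted p = 0.0985 with an estimated correlation). Of 38 p53 targets, 20 were higher and 1 lower (28 and 2 adjusted over the list alone, median 0.75, adjusted p = 6.75e-15, adjusted p = 0.258 with an estimated correlation). Of the 25 lists, 7 ranked higher and 7 lower, and 0 of these passed with an estimated correlation. The TLR and NF-kB list was also higher than in M-CSF, with 19 of 36 genes higher and 0 lower (27 and 0 adjusted over the list alone, median 0.79, adjusted p = 1.51e-17, adjusted p = 0.0739 with an estimated correlation). The stress response list ranked below its M-CSF level, with 8 of 29 genes lower and 3 higher (13 and 4 adjusted over the list alone). Its median was -0.28 (camera adjusted p = 0.00173, adjusted p = 0.465 with an estimated correlation). The count of 2110 became 1158 without M-CSF replicate 1, 1353 without M-CSF replicate 2, 1197 without FSL-1 + nutlin-3a replicate 1 and 1264 without FSL-1 + nutlin-3a replicate 2.

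Many genes passed in both of the main comparisons. Of 867 genes that rose with FSL-1, 269 (31%) fell when nutlin-3a was added, against 35.7 for independent lists of these sizes, and 35 rose further, against 20.6. Of 654 genes that fell with FSL-1, 87 (13.3%) rose with nutlin-3a, against 15.6, and 96 (14.7%) fell further, against 26.9. Csf1, Ccl7, Ccl12, Clec4e, Ptgir and Cox6a2 were among those that rose and then fell, Slc40a1, Plxdc2 and Il12rb2 among those that fell and then rose, and Itgal and Mmp9 rose in both. Because the FSL-1 arrays enter both comparisons with opposite sign, unchanged groups were simulated 100 times. Across genes, which are not independent replicates, the log2 changes correlated at -0.336 (simulated mean -0.5), and their covariance was -0.0423 against a simulated mean of -0.0117, a difference of -0.0307. The FSL-1 arrays were then divided, 1 for each comparison, an alternative chosen after seeing the data. With FSL-1 replicate 1 set against M-CSF and replicate 2 against nutlin-3a, 71 genes rose and then fell (3.94 for independent lists), 4 fell and then rose (0.495), 22 were called in the same direction (3.12) and the covariance was -0.0283. With the arrays exchanged, 71 rose and then fell (3.87), 9 fell and then rose (0.502), 17 were called in the same direction (2.79) and the covariance was -0.0312. In these fits each comparison has 1 FSL-1 array, and fewer genes were called (463 and 362, then 451 and 352). The count of 356 genes called in opposite directions became 164 without M-CSF replicate 1, 94 without FSL-1 replicate 1, 85 without FSL-1 replicate 2, 171 without FSL-1 + nutlin-3a replicate 1 and 166 without FSL-1 + nutlin-3a replicate 2.

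**Figure D3:**
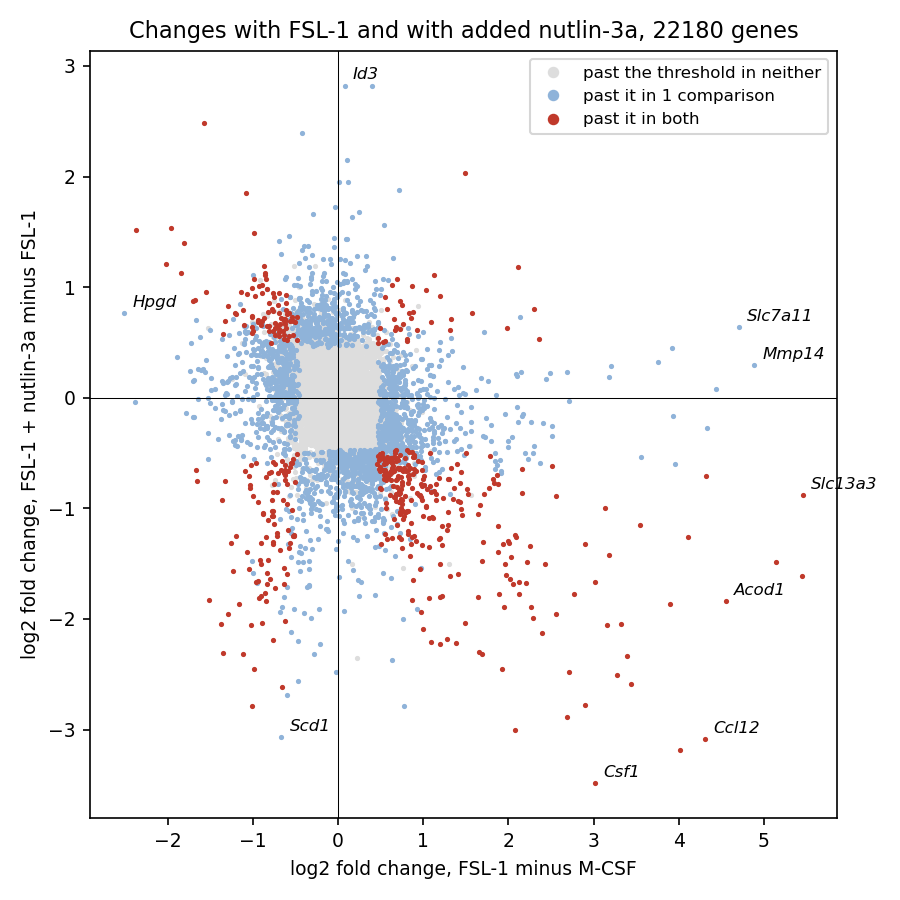
Log2 fold change with FSL-1 (horizontal axis) against log2 fold change on adding nutlin-3a (vertical axis) for 22180 genes, 1 point per gene; red points passed an adjusted p of 0.05 in both comparisons, blue in 1 and grey in neither. The lower right part holds the 269 genes that rose with FSL-1 and fell with nutlin-3a.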

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

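The tests of explanations in this part were chosen after the results had been seen. Probe sets without a gene name lie outside the comparisons of genes, and some of them passed an adjusted p of 0.05: 24 of 9055 with FSL-1 against M-CSF, 17 with nutlin-3a added to FSL-1, and 29 with FSL-1 + nutlin-3a against M-CSF. With FSL-1, probe set 17341276 had a log2 change of 6.20 (from 4.58 to 10.79) and probe set 17437213 a change of 3.71, while 17309141 had -1.79 and 17300044 had -1.78. What they measure is not analysed here. Among the 1814 probe sets that name several genes, 56, 65 and 86 passed in the same comparisons.

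Mitosis and cytokinesis genes were lower with FSL-1 than with M-CSF, with a median log2 change of -0.635 over 61 genes. Array scaling would move genes of the same level alike, yet 0 of 10000 random lists matched on level had a median as low. The lowest random median in the deposited values was -0.193. The count was also 0 after quantile normalization once more and after centring. Centring shifts all genes of an array equally, so it could not alter this outcome. Random lists ignore the correlation among these genes (estimated at 0.341 in the mitosis list). They therefore speak only to scaling, not to whether the list fell as a group. Dividing myeloid progenitors left in the M-CSF cultures could bring transcripts such as Mpo, Elane, Prtn3 and Ctsg. These 4 of 4 genes (4.70, 5.28, 4.85 and 3.94) lay below the median of all genes (5.51) on both M-CSF arrays. Of 19 progenitor markers, 0 were called lower with FSL-1. The median of all genes is not a detection limit, and dividing precursors without these markers would be missed, so this cannot decide the question. What stays open is dividing precursors in the M-CSF cultures, and, untested, an effect of FSL-1 on division, a lower amount of M-CSF in the FSL-1 wells, and the sort gate.

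Of the genes that rose with FSL-1, 269 fell when nutlin-3a was added. Noise of the shared FSL-1 arrays is argued against as the whole cause by dividing these arrays between the comparisons, since covariances of -0.0283 and -0.0312 were found where unchanged groups gave -0.000802 to 0.00072 in 100 simulations, and 71 and 71 genes rose and then fell (3.94 and 3.87 for independent lists), although calls in the same direction also exceeded independence (22 and 17, against 3.12 and 2.79); a culture shared by both FSL-1 arrays may still matter, as the labels leave it open. The simulated arrays varied independently, while deviations of same-numbered M-CSF and FSL-1 arrays correlated at -0.188, so the simulated range may be too narrow. Both divided fits also took their spread from the same M-CSF and FSL-1 + nutlin-3a arrays, so independent lists may understate joint calls. A uniform loss of the FSL-1 response, as from a share of cells that did not respond, would lower the 81 genes raised over 4-fold by about the same share. Their nutlin-3a changes had an SD of 1.07, against a median standard error of 0.151 and at most 0.253 in 1000 simulations with 1 common share, with 45 lower, 3 higher and 33 not past the threshold. The simulations held no other effect of nutlin-3a, so they argue only against a uniform loss as the sole change. On unlogged values, the 81 genes lost a median of 55.2% of their increase (quartiles 12.7% and 84.3%). Shares of the log2 changes would differ. What stays open, as hypotheses, is an effect of nutlin-3a on part of the response, and a uniform loss beside other effects. Csf1 lost 104% of its increase and Ccl7 94.9%, again on unlogged values. Mmp14 and Slc7a11 lay above their FSL-1 levels (log2 changes of 0.30 and 0.64, not past the threshold).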

How the results depend on the processing

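The crossed pairing and the division of the FSL-1 arrays below were chosen after seeing the data; the other alternatives were fixed beforehand. No gene called in the FSL-1 or nutlin-3a comparison changed sign in any of them, while the counts moved. The counts for FSL-1 against M-CSF, nutlin-3a added to FSL-1, and FSL-1 + nutlin-3a against M-CSF were 2744, 2658 and 3337 with trend and robust eBayes, and 2682, 2579 and 3290 among genes above the median level. With a milder filter on dim genes the first and second were 2313 and 2189. Opposite calls, 356 as reported, were 866, 816 and 632 in these settings. The filters test fewer genes, and the cause of the rise with eBayes was not tested. With the FSL-1 arrays divided between the comparisons they were 75 and 80, where each comparison has 1 FSL-1 array. With a fold of at least 1.5 the counts were 1255, 1145 and 1623.

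Leaving out 1 array gave 451 to 1299, 352 to 1212 and 1158 to 1529 genes, 85 to 267 opposite calls, and 14 to 17, 9 to 15 and 12 to 16 lists past camera; fewer samples enter these fits. Signs turned for genes and lists near 0, and the cause was not tested. For FSL-1 against M-CSF, Ocstamp was -0.00199 with centred arrays, Dcstamp -0.055 and Ocstamp -0.116 without M-CSF replicate 1, and -0.121 and -0.0949 without FSL-1 replicate 1, against a Dcstamp value of 0.338 without FSL-1 replicate 2 and an Ocstamp value of 0.177 without M-CSF replicate 2; camera turned for the replication list without M-CSF replicate 2 (median -0.00301, against -0.272 without M-CSF replicate 1). For nutlin-3a, Dcstamp was 0.139 without FSL-1 replicate 1 and -0.32 without FSL-1 replicate 2, and Ocstamp 0.14 without FSL-1 replicate 1, -0.11 without FSL-1 replicate 2 and -0.0926 without FSL-1 + nutlin-3a replicate 2. In the nutlin-3a comparison the TLR, cholesterol and matrix lists lost their camera call after quantile normalization, and these and the interferon list under both filters. The matrix list also lost it with array weights, and its median was 0.0369 among genes above the median level (adjusted p from 0.0512 to 0.971 in the settings that ended the call).

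With the replicate number as a block the counts were 1167, 1005 and 1725. The numbers do not show pairing of same-numbered arrays. Their deviations correlated at -0.188 between M-CSF and FSL-1, 0.0175 between M-CSF and FSL-1 + nutlin-3a, and -0.0248 between FSL-1 and FSL-1 + nutlin-3a. The first value means that differently numbered arrays of M-CSF and FSL-1 deviated somewhat alike. Variation shared across these 2 groups therefore stays possible. With the M-CSF numbers crossed the block gave 1278, 1148 and 1971 genes. Detection calls are not analysed here, so changes of dim genes have an unknown floor.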

Other observations

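The lists in this part, and their tests, were chosen after the data had been seen. Genes of amino acid transport and of serine and one-carbon synthesis were looked at with FSL-1. Of 23 measured, 7 rose and 0 fell with FSL-1 (median log2 change 0.52, camera adjusted p = 3.58e-08, adjusted p = 0.328 with an estimated correlation). Replication-dependent histone genes had 3 of 9 lower with FSL-1 (adjusted p = 0.0668), and 1 higher and 2 lower with nutlin-3a (adjusted p = 0.182). Progenitor markers had 0 of 19 called with FSL-1 and 1 lower with nutlin-3a.

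Sex-linked genes were looked at as a check of the samples. Xist lay between 9.48 and 10.43 (log2) on the 6 arrays, and the Y-linked genes Eif2s3y, Kdm5d and Uty at or below 3.90.

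The low Slc7a5, Psat1 and Mthfd2 with nutlin-3a gave the hypothesis that amino acid transport and serine and one-carbon genes may fall as a group. Without these 3 genes, 12 of the other 20 fell and 0 rose (median -0.84), and camera placed them below other genes (adjusted p = 1.07e-12 over the 3 hypotheses tested). With an estimated correlation the adjusted p was 0.187, so the hypothesis stays open. Psat1 and Mthfd2 also belong to the stress response list, which had been seen to fall with nutlin-3a on the same arrays. How many genes the lists share is not given here, so this is not independent of that result.

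The high Id1, Id3 and Smad6 with nutlin-3a gave the hypothesis that BMP and SMAD targets may rise as a group. Of the other 13 genes, 2 rose and 0 fell (median 0.03, adjusted p = 0.546, and adjusted p = 0.754 with an estimated correlation), so no rise of the list beyond the genes that gave the idea was detected. The low Scd1 and Fads2 gave the hypothesis that fatty acid synthesis genes may fall together. Of the other 18 genes, 2 rose and 1 fell (median 0.04, adjusted p = 0.672, and adjusted p = 0.754 with an estimated correlation), so no fall of the list was detected either. Smad6 and Fads2 were named for these tests after their values were seen.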
